A study of Mus musculus with 57 samples.

How the data were processed

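Gene expression was measured in the visual cortex of wild-type mice by MARS-Seq, a method that sequences tags from the 3′ ends of polyadenylated transcripts, in 57 libraries of total RNA. Per the labels, mice were housed under 12 h of light and 12 h of darkness, and tissue was collected at Zeitgeber times (ZT, hours after the usual lights-on). In 27 libraries the day of collection had the usual light. In 30 libraries the lights did not come on that day. The ZT0 group, collected at the usual lights-on, is labelled dark and served as the baseline before light for both arms. The groups and replicate numbers were taken from the labels, which call the samples biological replicates. Nothing says outright that each came from a separate animal, so p-values measure the spread between these samples. Batch, sex and age are not given in the sources used here.

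Reads were trimmed with cutadapt, aligned with STAR 2.5.2b to the mm10 build of the mouse genome and normalised with DESeq2, per the submitters' processing notes. The annotation, the treatment of molecular identifiers and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes could share counts. The deposited table held 1 signal value per gene and library, which are gene counts divided by a size factor per library, as the authors made them. The table had 24421 rows. Date names, as a spreadsheet writes for some gene symbols, stood in 27 rows and were left out. These took 0.294% to 0.363% of a library's reads. Of the 24394 named genes, 18645 had a read in some library.

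The value of 1 read in each library was taken from the spacing of its low values. After division by it, 100% of values lay within 0.01 of a whole number, with a largest distance of 0.0065. Reads were recovered in this way for all 57 libraries. The recovered totals ran from 1.64 to 4.31 M reads (M, mega), with a median of 2.75 M in dark and 2.76 M in light libraries. Whether these are reads or unique molecules is not given in the sources used here. With this depth, a gene at a mean value of 10 rests on few reads per library, and its fold change is the less precise for it. All 81 replicate pairs within groups differed by more than counting noise, with chi-square per degree of freedom from 2.15 to 7.01, so that no library was a copy of another.

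Genes with a mean value of at least 10 over all libraries were tested, which left 10526. The main test was limma 3.58.1 with a mean-variance trend on log2(value + 1), in R 4.3.3. All 57 libraries in 15 groups shared 1 estimate of the spread per gene, and no covariate was used. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Light was compared with dark at ZT1, ZT3, ZT7.5, ZT11.5, ZT13, ZT15 and ZT18. Further contrasts were ZT1 against ZT0 (dawn) and ZT13 against ZT11.5 (dusk) in each arm, and the difference between the dusk changes of both arms. Moderated F tests covered change over the 8 dark times, change over the 7 light times, and a light-dark difference that varied with time. Rhythms of 24 h were fitted with cosine and sine terms per arm. Since sampling spanned 18 h, peak times are estimates under that assumed period.

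Choices of tests, filters, gene lists and alternatives were made before the data were examined, except where stated. There were 24 gene lists: immediate-early, activity effector, clock, glucocorticoid, heat shock, endoplasmic reticulum (ER) chaperone, cholesterol synthesis, oxidative phosphorylation, ribosomal protein, excitatory neuron, interneuron, astrocyte, oligodendrocyte, oligodendrocyte precursor, microglia, endothelial, mural, meningeal fibroblast, choroid plexus, blood, hippocampus, striatum, thalamus and sex genes. Lists with at least 3 tested members, 22 in all, were tested with camera (limma) at its preset correlation of 0.01, adjusted over lists within a contrast. The test was repeated with a correlation estimated from the data. Blood and sex lists had 1 tested member each. Enrichment of lists among genes changing over time was tested with Fisher's exact test against all genes tested. That test takes genes as independent. Members of a list measured in the same libraries need not be, so its p-values can be too small.

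The genes named were set by a rule. For each contrast it took up to 10 of the largest rises and falls among genes passing the test, every member of the immediate-early, activity effector, clock and glucocorticoid lists, Cirbp and Rbm3, and the 4 members with the smallest p of each other list. For F tests it took the 10 smallest p and the same lists. Unnamed gene models and genes with near-identical copies were skipped.

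The alternatives were a pseudocount of 5, no filter on low values, a minimum mean of 50, TMM rescaling, a fit to only the groups compared, the replicate number as a block, each library left out in turn, the camera test with an estimated correlation, and count models on the recovered reads (edgeR 4.0.16 quasi-likelihood test, DESeq2 1.42.0). Alternatives chosen after seeing the data were terms for Xist status, for log2 Ttr, for the mean log2 level of Prkcd and Tnnt1, for the first axis of variation within groups and for replicates 3 and 4 against 1 and 2 within each arm, and a fit without the 7 libraries under 2 M reads.

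The procedure was tested on simulated data drawn from the real means and library sizes, with changed genes planted among the 10526 tested. Genes were drawn independently of each other, without the structure between libraries described below. The numbers of unchanged genes called may thus be too low for the real libraries. For light against dark at ZT1, it called 35.8% of 67 genes changed 1.5-fold, 85.1% of 67 changed 2-fold and 98.5% of 66 changed 4-fold, with 6 unchanged genes called. At ZT7.5 the shares were 53.7%, 77.6% and 98.5%, with 10 unchanged genes called. For the tests over time, the planted genes followed a 24 h cosine in the dark arm alone. Their folds of 1.5, 2 and 4 were from trough to peak. A light-dark difference that varied with time was called for 11.9%, 52.2% and 87.9% of them. Change over dark times was called for 50.7%, 76.1% and 98.5%. A response to light at a single time was not planted for these tests. Recovery of reads was exact for 100% of values, which were simulated as unrounded multiples of a known step. It does not test the unit of the deposited values. Gene positions are from the GENCODE M21 annotation of GRCm38, the assembly that mm10 denotes.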

Results

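The data comprised 57 libraries of mouse visual cortex RNA in 15 groups. The dark arm, whose lights stayed off on the day of collection, had 4 libraries at each of ZT0, ZT3, ZT7.5, ZT11.5, ZT15 and ZT18, and 3 at ZT1 and at ZT13. The light arm had 4 libraries at each of ZT1, ZT3, ZT7.5, ZT11.5, ZT13 and ZT15, and 3 at ZT18. Depth per library ran from 1.64 to 4.31 M reads. Values below are deposited normalised counts, as mean ± SD over the n libraries of a group, and log2 differences with adjusted p-values are from limma over 10526 genes. The comparisons address which cortical transcripts follow light at each time of day, and which change over the day with and without light.

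Libraries differed in ways the labels do not describe. Ttr, a transcript abundant in choroid plexus, ran from 53.5 to 20500 between libraries, and Malat1, a nuclear noncoding RNA, from 14.9 to 483. Xist, the RNA of the inactive X chromosome, was above 20 in 29 libraries, with a lowest value of 31.5 among them, and at most 4.25 in the other 28. Reads on 4 Y-linked genes summed to at most 2 in the libraries with Xist above 20 and to 17 to 50 in the others. This is the pattern of female and of male tissue. Most groups held both kinds, but all 4 libraries of the Light ZT13 group had Xist above 20, against 1 of 3 at Dark ZT13 and 2 of 4 at Light ZT11.5. Replicates 1 and 2 stood apart from 3 and 4 within an arm. Between libraries of different groups of the light arm, deviations from the group means correlated at 0.11 on average within these pairs of numbers and at -0.11 across them (one-sided permutation p = 5e-05). In the dark arm the values were 0.038 and -0.038 (permutation p = 0.00055). Malat1 was lower in replicates 3 and 4 in 7 of 7 light groups, with a mean log2 difference of -1.83, and higher in 7 of 8 dark groups, with 0.85. Xist was above 20 in replicates 3 and 4 and not in 1 and 2, in all but 2 libraries.

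After 1 h of light, activity-induced transcription factors were far higher than at the same hour without light. Egr2, a zinc finger factor, reached 185 ± 25.1 (n = 4) in light and 14.2 ± 1.16 (n = 3) in dark libraries, a log2 difference of 3.61 (SE 0.58, adjusted p = 9.5e-05). Fos, a component of the AP-1 factor, was 389 ± 76 against 48.9 ± 6.98 (log2 difference 2.96, SE 0.37, adjusted p = 2.4e-07), and Egr1 was 2410 ± 97.2 against 778 ± 82.3 (1.63, adjusted p = 6e-09). Arc, which encodes a synaptic cytoskeleton-associated protein, was 1770 ± 461 against 317 ± 34.4 (2.45, adjusted p = 4.1e-06). For these 4 genes all light libraries lay above all dark libraries. Fos lies on chromosome 12 (85473890 to 85477273, plus strand, GRCm38), Egr1 on 18 (34859823 to 34864984, plus), Egr2 on 10 (67535475 to 67542188, plus) and Arc on 15 (74669083 to 74672570, minus), and all are protein-coding.

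Of the 19 immediate-early genes tested, 13 rose over all genes and 15 rose adjusted over the list alone, with a median log2 difference of 1.63. Other members were the nuclear receptor Nr4a1 (1350 ± 251 against 268 ± 36.8), the AP-1 factor Junb (2040 ± 672 against 462 ± 63.3), Egr4 (779 ± 101 against 190 ± 15.6) and the MAP kinase phosphatase Dusp1 (275 ± 85.7 against 85.7 ± 17.7). The neuronal factor Npas4 did not pass, with a log2 difference of 1.71 (adjusted p = 0.14). Outside the list, the matricellular gene Cyr61 rose (69.1 ± 17.3 against 12.3 ± 3.52), as did the pseudokinase gene Trib1 (156 ± 9.97 against 42.2 ± 10.2). Of 22 activity effector genes, which encode secreted, synaptic and signalling proteins, Gadd45b (213 ± 39.2 against 100 ± 15.8) and Plk3 (log2 difference 0.90, adjusted p = 0.013) rose, and 10 rose adjusted over the list alone. Of 16 clock genes, Per1, a light-responsive repressor of the clock, rose from 178 ± 14.6 to 389 ± 90.6 (1.09, SE 0.19, adjusted p = 0.00031), and 3 rose adjusted over the list alone.

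In all, 27 genes were higher and 0 lower in light at ZT1, with 488 at an unadjusted p under 0.05. The immediate-early and activity effector lists were higher by camera (adjusted p = 6.1e-68 and 1.4e-12) and remained so with an estimated correlation (adjusted p = 9e-10 and 3.9e-06). The clock, oligodendrocyte and microglia lists were higher (adjusted p = 0.0076, 0.015 and 0.0076) and the ribosomal protein list lower (0.0031). None of these passed with an estimated correlation, where the adjusted p = 0.072, 0.48, 0.12 and 0.38 in that order. Without Dark ZT1 replicate 2 the count was 17, and Egr3 (adjusted p = 0.0633), Klf4 (0.172) and Plk3 (0.162) were not called. Klf4 was also not called without Light ZT1 replicate 4 (0.0636), or with only the groups compared, nor Plk3 without Dark ZT1 replicate 3 (0.0727) or Light ZT1 replicate 1 (0.108) or 4 (0.0864).

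**Figure D1:**
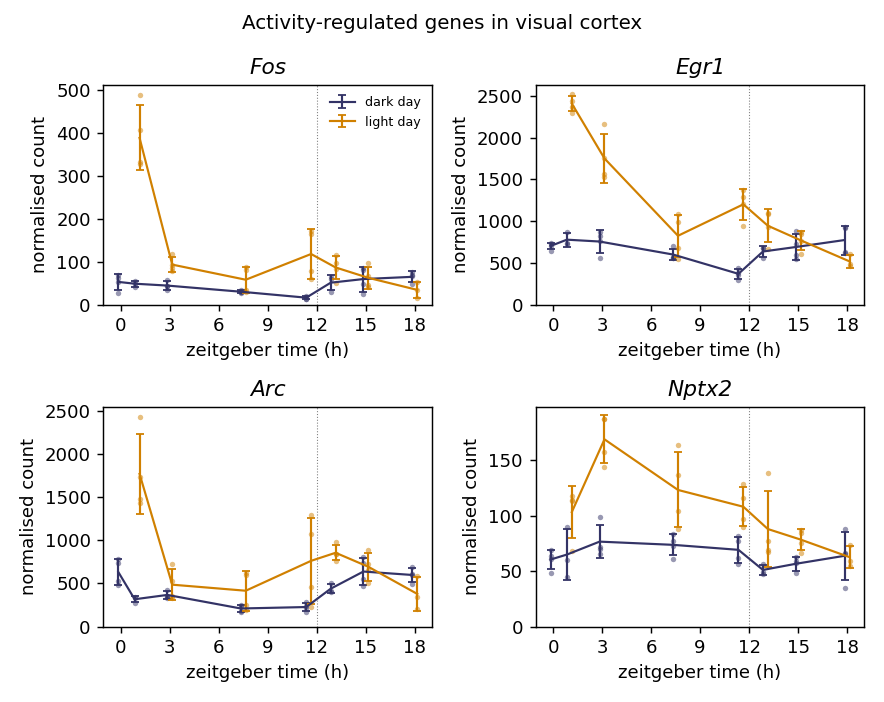
Normalised counts of Fos, Egr1, Arc and Nptx2 (vertical axes) against Zeitgeber time in hours (horizontal axes), with 1 point per library and group means ± SD, for the day with light and the day kept dark, and a dotted line at the usual lights-off. Fos, Egr1 and Arc peak at Light ZT1 with means of 389, 2410 and 1770, and Nptx2 peaks at Light ZT3 with a mean of 169.

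At 3 h of light genes of the Egr family were higher in light, as was the synaptic gene Nptx2. Egr2 was 33.2 ± 5.32 in light and 8.7 ± 7.77 in dark libraries (n = 4 each; log2 difference 2.46, adjusted p = 0.036), Egr1 1750 ± 290 against 756 ± 136 (1.22, adjusted p = 6.1e-06), and Egr3 338 ± 37.4 against 168 ± 21.6 (1.01, adjusted p = 7e-07). Nptx2, a neuronal pentraxin that gathers AMPA receptors at synapses, rose to 169 ± 21.4 from 76.7 ± 15.2 (1.14, SE 0.21, adjusted p = 0.004). At ZT1 it was 104 ± 23.5 against 65 ± 23.2 and did not pass (0.69, adjusted p = 0.54). Nptx2 lies on chromosome 5 (144545902 to 144557478, plus strand, GRCm38). Also higher were the AP-1 gene Fosl2 (59.2 ± 13.8 against 25.6 ± 4.12), the cell cycle inhibitor Cdkn1a (153 ± 16 against 90.6 ± 8.1), the imprinted gene Mest (80 ± 9.01 against 47.9 ± 3.65) and Rspo1, which encodes a Wnt pathway agonist (103 ± 14.4 against 62.1 ± 5.01).

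Of the immediate-early genes 6 of 19 rose, and adjusted over the list alone 8 rose and 1 fell (camera adjusted p = 1.9e-13, and 0.0027 with an estimated correlation). Of the activity effectors 3 of 22 rose, and 7 adjusted over the list alone (adjusted p = 1.9e-09, and 0.00012 with an estimated correlation). Excitatory neuron genes were higher as a list, with Rspo1 called among 16 and 7 adjusted over the list alone (adjusted p = 0.00033, and 0.00085 with an estimated correlation). Higher cholesterol synthesis and oligodendrocyte lists and lower ribosomal protein and choroid plexus lists passed with the preset correlation (adjusted p = 0.0022, 0.0014, 0.0098 and 0.034) and not otherwise (adjusted p = 0.18, 0.25, 0.45 and 0.45 with an estimated correlation). The choroid plexus list had a median log2 difference of -1.54, with Ttr from 439 to 5480 in Dark ZT3 libraries and from 255 to 1090 in Light ZT3 libraries.

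In all, 13 genes were higher and 0 lower at ZT3, with 731 at an unadjusted p under 0.05, 23 called by DESeq2, 4 without the filter on low values and 8 with the thalamic genes Prkcd and Tnnt1 as a term. Without the filter 7 of the 11 named calls were lost: Egr2, Fosl2, Cdkn1a, Mest, Rspo1, Fosb and the phosphatase gene Dusp14. With Prkcd and Tnnt1 as a term 4 were lost (Egr2, Cdkn1a, Mest and Rspo1), with only the groups compared also 4 (Egr2, Mest, Rspo1 and Dusp14), and by DESeq2 Egr2. The count fell to 5 without Dark ZT3 replicate 2 or 4 or Light ZT3 replicate 2, and to 6 without Dark ZT3 replicate 3 or Light ZT3 replicate 3. Egr1, Egr3, Egr4 and Nptx2 kept their calls whichever library was left out. The calls of Egr2 (adjusted p up to 0.458, without Dark ZT3 replicate 3), Cdkn1a (0.205), Mest (0.196), Rspo1 (0.285, these without Light ZT3 replicate 3) and Fosl2 (0.116, without Light ZT3 replicate 2) did not.

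At ZT7.5 no gene passed. Nptx2 was 123 ± 34 in light and 73.8 ± 9.41 in dark libraries (n = 4 each; log2 difference 0.70, adjusted p = 0.71), and Nr4a1 was 347 ± 122 against 210 ± 31.1 (0.67). As a list, the activity effectors were higher, with a median log2 difference of 0.22, 0 of 22 members called and 6 higher adjusted over the list alone (camera adjusted p = 3.4e-06, and 0.0024 with an estimated correlation). The immediate-early list was higher with the preset correlation (median 0.41, 0 of 19 called, 2 adjusted over the list alone, adjusted p = 0.00011), with adjusted p = 0.24 with an estimated correlation. Its mean log2 level was 5.958 and 6.018 in Light ZT7.5 replicates 1 and 2, 6.519 and 6.567 in replicates 3 and 4, and 5.842 to 6.049 in the dark libraries. Arc was 188 and 248 in the former pair, 603 and 623 in the latter, and 166 to 255 in the dark libraries. Light minus dark was 0.13 within replicates 1 and 2 and 0.54 within replicates 3 and 4. Oligodendrocyte, oligodendrocyte precursor and thalamus lists were higher in the same way (adjusted p = 0.049, 0.044 and 0.049), with adjusted p = 0.5, 0.083 and 0.5 with an estimated correlation. The count of 0 by limma stood beside 613 genes at an unadjusted p under 0.05, and edgeR and DESeq2 also called 0.

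At ZT11.5, near the end of the day, immediate-early genes were again far apart between the arms. Egr2 was 29.2 ± 5.48 in light and 1.83 ± 1.29 in dark libraries (n = 4 each; log2 difference 3.57, adjusted p = 6.5e-05), Fos 118 ± 57.9 against 16.3 ± 3.65 (2.66, adjusted p = 1.3e-06), Egr1 1200 ± 183 against 369 ± 60.2 (1.70, adjusted p = 3.2e-10) and Nr4a1 527 ± 217 against 204 ± 11.4 (1.27, adjusted p = 9.2e-05). For Fos, Egr1 and Egr2 all light libraries lay above all dark libraries. Sh2b3, an adaptor protein of cytokine signalling, was also higher (40.8 ± 11 against 16.5 ± 3.82), and Tmem138, a gene of the primary cilium, was lower (34.9 ± 5.27 against 65.7 ± 7.37, log2 difference -0.90, adjusted p = 0.033). The other lower gene, Rpl37rt, is a ribosomal protein retrogene with near-identical copies, lies outside the naming rule and was chosen after its values were seen.

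Of the 19 immediate-early genes 9 rose, and 14 adjusted over the list alone (camera adjusted p = 3e-29, and 2.1e-05 with an estimated correlation). Of the activity effectors 0 of 22 passed over all genes and 9 rose adjusted over the list alone (median 0.32, adjusted p = 7.7e-09, and 0.00011 with an estimated correlation). Glucocorticoid-responsive genes were lower in light, with 0 of 15 called, 3 lower adjusted over the list alone and adjusted p = 0.0015, and thalamus genes were lower with 0 of 5 called, 2 lower adjusted over the list alone and adjusted p = 0.0051. Both had adjusted p = 0.29 with an estimated correlation. Prkcd, a thalamic gene, ran from 41.5 to 166 in dark and from 53.6 to 72 in light libraries, and Tnnt1 from 19.8 to 140 and from 14.4 to 39.1.

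In all, 14 genes were higher and 2 lower at ZT11.5, with 844 at an unadjusted p under 0.05 and 41 called by DESeq2. With terms for replicates 3 and 4 against 1 and 2 in each arm the count was 25. With Prkcd and Tnnt1 as a term the count was 11, and the named calls lost were Arc (1.46, then 1.17 with adjusted p = 0.192), Junb (1.03, then 0.83 with adjusted p = 0.23), Egr3 (0.55, then 0.50 with adjusted p = 0.161) and Tmem138 (-0.90, then -0.83 with adjusted p = 0.148). With only the groups compared 5 of the 12 named calls were lost (Arc, Junb, Egr3, Fosb and Gadd45a), and without the filter on low values 2 (Arc and Junb). Without Dark ZT11.5 replicate 3 the count was 7 and without Light ZT11.5 replicate 3 it was 8. Egr1, Egr2, Egr4, Fos, Nr4a1 and Sh2b3 kept their calls whichever library was left out, while Arc (0.277) and Junb (0.302) were not called without Light ZT11.5 replicate 3, Egr3 (0.266) without Dark ZT11.5 replicate 3, nor Tmem138 (0.15) without Light ZT11.5 replicate 1.

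After lights-off, 4 genes passed at ZT13 and none at the later times. Mest and Midn were also called at ZT1 and ZT3, and Klf10 and Scube1 at neither. At ZT13 the zinc finger gene Klf10 was 127 ± 17.9 in the light arm (n = 4) and 57.3 ± 4 in the dark arm (n = 3; log2 difference 1.13, adjusted p = 0.0054). Scube1, a secreted EGF-domain protein, was 82.2 ± 12.1 against 39.4 ± 5.75 (1.04, adjusted p = 0.0028), Mest 47.9 ± 10.3 against 24 ± 4.45 (0.96, adjusted p = 0.0039) and the nuclear protein gene Midn 317 ± 47.1 against 210 ± 25.9 (0.59, adjusted p = 0.0068). The activity effector list was higher at ZT13, with 0 of 22 called and 6 adjusted over the list alone (adjusted p = 9.6e-06, and 0.0039 with an estimated correlation). It was also higher at ZT15, with 0 called and 3 adjusted over the list alone (adjusted p = 0.00017, and 0.017 with an estimated correlation).

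At ZT13 other lists passed with the preset correlation and not with an estimated one. Immediate-early genes were higher, with 0 of 19 called and 7 adjusted over the list alone (adjusted p = 0.00017), as were heat shock, ER chaperone and interneuron genes (adjusted p = 0.003, 0.00043 and 0.025), each with adjusted p = 0.11 with an estimated correlation. Ribosomal protein, oxidative phosphorylation and mural cell genes were lower (adjusted p = 0.00017, 0.011 and 0.012), again each with adjusted p = 0.11 with an estimated correlation. Oligodendrocyte and hippocampus genes were lower (adjusted p = 0.046 and 0.012), with adjusted p = 0.38 and 0.2 with an estimated correlation. The oligodendrocyte list did not pass with terms for replicates 3 and 4 against 1 and 2 in each arm. Libraries with Xist above 20 made up 4 of 4 in the light arm and 1 of 3 in the dark arm at this time. The 4 calls stood beside 871 genes at an unadjusted p under 0.05. There were 7 without the filter on low values, 2 with only the groups compared, 1 without the libraries under 2 M reads, 2 without Dark ZT13 replicate 1 and 1 without Light ZT13 replicate 2. Scube1, Mest and Midn were not called with only the groups compared, Klf10, Mest and Midn without the libraries under 2 M reads, nor Mest by DESeq2. Klf10 was not called without Dark ZT13 replicate 3 (adjusted p = 0.0791) or Light ZT13 replicate 2 (0.0512), and Scube1 (0.0557), Mest (0.0747) and Midn (0.155) were not called without Dark ZT13 replicate 1.

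At ZT15 the secretory granule gene Scg2 was 730 ± 28.1 in the light arm and 580 ± 38.3 in the dark arm (n = 4 each), which did not pass (log2 difference 0.33, adjusted p = 0.59). ER chaperone, interneuron and thalamus lists were higher (adjusted p = 0.0052, 0.0069 and 0.0069) and oligodendrocyte and meningeal fibroblast lists lower (both 0.021), with adjusted p = 0.17, 0.089, 0.26, 0.46 and 0.23 with an estimated correlation. At ZT18 Fos was 34.3 ± 18.3 (n = 3) in the light arm and 64.9 ± 12.6 (n = 4) in the dark arm, which did not pass (-1.03, adjusted p = 0.36). The immediate-early list was lower (median -0.36, 0 of 19 called, also adjusted over the list alone, adjusted p = 0.00097) and the glucocorticoid list higher (adjusted p = 0.046), both with adjusted p = 0.63 with an estimated correlation. By limma 0 genes passed at ZT15 and 0 at ZT18, with 464 and 964 at an unadjusted p under 0.05. At ZT15 edgeR and DESeq2 called 0, and at ZT18 edgeR called 0, DESeq2 1, the fit without a filter on low values 7, that with only the groups compared 1, and limma 1 without Dark ZT18 replicate 1 or replicate 3.

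The light-dark difference itself varied with time for 19 genes, led by immediate-early genes. The smallest adjusted p-values belonged to Egr1 (4.1e-09), Egr4 (1.3e-08), Nr4a1 (3.6e-07) and Fos (2e-06), each highest at Light ZT1. Of the immediate-early list 11 of 19 passed, and 16 adjusted over the list alone. Of the activity effectors 1 of 22 passed, and 6 adjusted over the list alone. There were 723 genes at an unadjusted p under 0.05, 39 called by DESeq2, 12 without the libraries under 2 M reads, and 11 without Dark ZT1 replicate 1. Within replicates 1 and 2 the mean level of the immediate-early list differed by 1.71 at ZT1, 0.50 at ZT3, 0.83 at ZT11.5, 0.52 at ZT13 and -0.50 at ZT18, and within replicates 3 and 4 by 1.32, 0.69, 1.22, 0.10 and -0.10. Genes called higher in light overlapped between times whose groups had no library in common. There were 7 shared by ZT1 and ZT3 (0.033 by independent lists), 10 by ZT1 and ZT11.5 (0.036), and 6 by ZT3 and ZT11.5 (0.017). The calls nonetheless shared 1 estimate of the spread per gene from all 57 libraries, and genes differ in how readily they pass. Independent lists thus understate the overlap to be expected without a shared response.

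From ZT0 to ZT1 on a day with light, activity-induced transcription factors rose over the hour. Egr2 rose from 10.4 ± 5.32 to 185 ± 25.1 (n = 4 each; log2 change 4.12, adjusted p = 6.3e-07), Egr1 from 702 ± 39.9 to 2410 ± 97.2 (1.78, adjusted p = 3.2e-11), Arc from 632 ± 151 to 1770 ± 461 (1.48, adjusted p = 0.01) and Per1 from 200 ± 27.1 to 389 ± 90.6 (0.93, adjusted p = 0.0015). The heat shock co-chaperone gene Dnajb1 rose from 322 ± 19 to 459 ± 43.7 (0.51, adjusted p = 0.0065). Hes5, a Notch target, was the gene that fell, from 186 ± 25 to 136 ± 3.01 (-0.44, adjusted p = 0.032). Of the immediate-early genes 13 of 19 rose, and 17 adjusted over the list alone (camera adjusted p = 6.6e-68, and 9.1e-10 with an estimated correlation). Of the activity effectors 3 of 22 rose, and 10 adjusted over the list alone (adjusted p = 1.8e-13, and 1.9e-06 with an estimated correlation). Clock, heat shock and ER chaperone lists rose (adjusted p = 0.0086, 0.014 and 0.014) and cholesterol synthesis and oligodendrocyte lists fell (9.2e-05 and 1e-04), with adjusted p = 0.059, 0.19, 0.2, 0.058 and 0.12 with an estimated correlation. In all, 31 genes rose and 1 fell, with 596 at an unadjusted p under 0.05, and Arc was not called without Light ZT1 replicate 1 (adjusted p = 0.0859), Dnajb1 without Light ZT1 replicate 3 (0.0671), nor Hes5 without Dark ZT0 replicate 1 (0.261) and in most other such fits, with only the groups compared or without the libraries under 2 M reads.

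Over the same hour without light, 0 of 19 immediate-early genes passed, also adjusted over the list alone (camera adjusted p = 0.95). Fos was 53.1 ± 18.6 at ZT0 (n = 4) and 48.9 ± 6.98 at ZT1 (n = 3; log2 change -0.04, adjusted p = 0.99). Arc was 632 ± 151 and then 317 ± 34.4, with all ZT1 libraries below all ZT0 libraries (-0.97, adjusted p = 0.33), and Btg2 39.7 ± 15.4 and then 22.5 ± 1.16 (-0.70, adjusted p = 0.45). The light-dark difference of Arc at ZT1 (2.45) was thus larger than its change from ZT0 in light (1.48). The genes that fell included Dhcr7, which encodes a late enzyme of cholesterol synthesis (121 ± 15.9 to 66.5 ± 13, -0.87, adjusted p = 0.0073), the small heat shock protein gene Cryab (997 ± 45.9 to 641 ± 97.1, -0.65, adjusted p = 0.0023) and the complement gene C1qc, made by microglia (400 ± 66 to 263 ± 40.7, -0.60, adjusted p = 0.0073). Oligodendrocyte genes fell as a list, with 0 of 10 called and 8 lower adjusted over the list alone, among them Opalin (179 ± 25.5 to 108 ± 25.4) and Mog (322 ± 2.79 to 223 ± 32). Cholesterol synthesis genes fell as a list, with 1 of 14 called and 4 adjusted over the list alone. Their camera adjusted p-values were 4.3e-08 and 2.7e-05, and both were 0.049 with an estimated correlation. Microglia genes were lower (1 of 8 called, adjusted p = 0.001) and ribosomal protein genes higher (adjusted p = 0.011), with adjusted p = 0.05 and 0.58 with an estimated correlation, neither passing.

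In all, 1 gene rose and 5 fell over this hour in the dark, with 929 at an unadjusted p under 0.05. Epb4.1l4aos rose and 1110008P14Rik and Tuba1a fell, all outside the naming rule and chosen after their values were seen. The counts by other fits were 6 by edgeR, 68 by DESeq2, 12 with a minimum mean of 50, 0 with only the groups compared, 14 without the libraries under 2 M reads and 16 with terms for replicates 3 and 4 against 1 and 2 in each arm. With Dark ZT0 replicate 1 left out the count was 1, with Dark ZT0 replicate 4 or Dark ZT1 replicate 1 it was 2, with Dark ZT1 replicate 2 it was 0 and with Dark ZT1 replicate 3 it was 21. Dhcr7, C1qc and Cryab each had adjusted p = 0.292 without Dark ZT1 replicate 2.

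**Figure D2:**
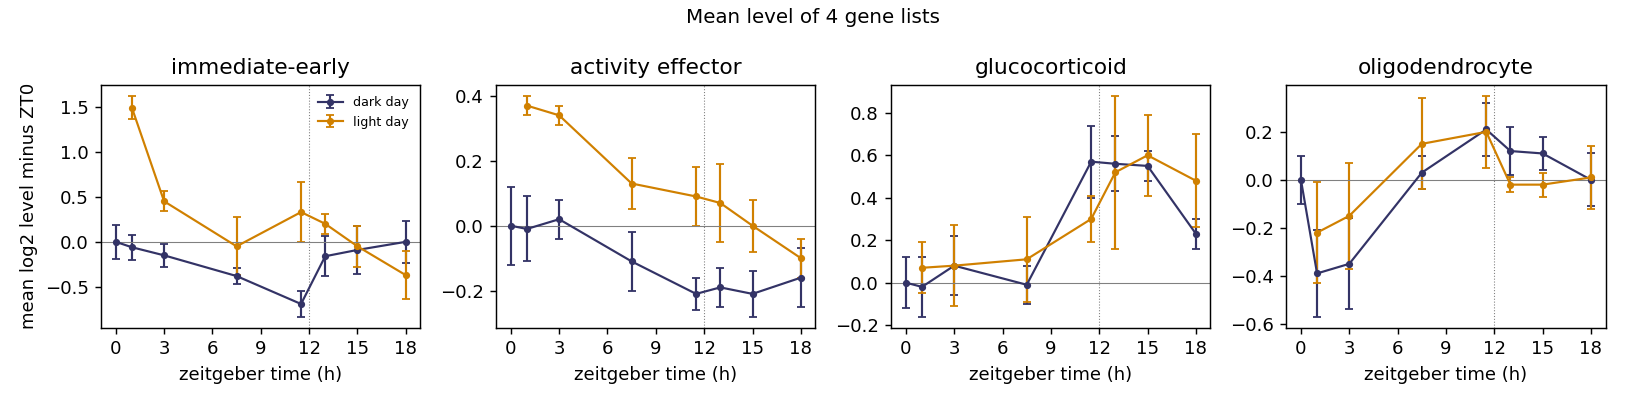
Mean log2 level of the immediate-early, activity effector, glucocorticoid and oligodendrocyte lists minus its ZT0 mean (vertical axes) against Zeitgeber time in hours (horizontal axes), as group means ± SD over libraries for the day with light and the day kept dark. The immediate-early list stands at 1.49 ± 0.13 at Light ZT1 and -0.69 ± 0.14 at Dark ZT11.5, and the glucocorticoid list at 0.57 ± 0.17 at Dark ZT11.5.

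Across lights-off, from ZT11.5 to ZT13 in the light arm, 27 genes changed. Grip2, a scaffold of AMPA receptors, rose from 36.7 ± 6.6 to 72 ± 10.5 (n = 4 each; log2 change 0.96, adjusted p = 3e-04), and Kcnj9, a potassium channel subunit, from 45.1 ± 8.78 to 75.5 ± 14.4 (0.73, adjusted p = 0.014). Gfap, the astrocyte filament gene, fell from 413 ± 53.2 to 262 ± 32.1 (-0.65, adjusted p = 0.014), the myelin gene Pllp from 450 ± 47.3 to 311 ± 22.2 and the interferon-induced Isg15 from 79.4 ± 15.6 to 40.8 ± 14.5 (-0.98, adjusted p = 0.029). Oxidative phosphorylation, ribosomal protein, oligodendrocyte and choroid plexus lists fell (adjusted p = 0.0028 each), with adjusted p = 0.11, 0.25, 0.25 and 0.25 with an estimated correlation. Clock, glucocorticoid and ER chaperone lists rose (adjusted p = 0.0058, 0.044 and 0.0034), with adjusted p = 0.11, 0.39 and 0.16 with an estimated correlation. The glucocorticoid list had mean log2 levels of 7.526 and 7.708 in Light ZT13 replicates 1 and 2 and of 6.931 and 7.087 in replicates 3 and 4, against 6.983 to 7.236 in the Light ZT11.5 libraries. Its member Sgk1 was 508 and 570 in the former pair and 173 and 205 in the latter. Ttr went from 4580 ± 4230 to 622 ± 936, and libraries with Xist above 20 from 2 of 4 to 4 of 4. With Xist status as a term, 4 of the 20 named calls were lost: Pllp (adjusted p = 0.0729), Srrt (0.0543), Tspan18 (0.0574) and Zkscan4 (0.0625).

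Of the 27 genes, 17 rose and 10 fell, with 1199 at an unadjusted p under 0.05, 34 called by edgeR, 99 by DESeq2, 43 with the replicate number as a block, 47 with terms for replicates 3 and 4 against 1 and 2 in each arm, 14 with a Ttr term, 14 with the term for Prkcd and Tnnt1 and 0 with only the groups compared, so that no named gene kept its call there. Of the 20 named calls 8 were lost with the Ttr term, Pllp and Isg15 among them, 9 with the term for Prkcd and Tnnt1, Pllp among them, and 5 without the filter on low values, Pllp again among them. The count was 3, 9, 10 and 4 without Light ZT11.5 replicates 1, 2, 3 and 4, and 70, 3 and 5 without Light ZT13 replicates 2, 3 and 4. In the dark arm the same interval gave 1 gene, Flywch1, a zinc finger gene, which rose from 166 ± 15.6 (n = 4) to 261 ± 17.1 (n = 3; 0.65, adjusted p = 0.021). Fos was 16.3 ± 3.65 and then 51.2 ± 18.1 (1.55, adjusted p = 0.13) and Egr1 369 ± 60.2 and then 636 ± 67.5 (0.79, adjusted p = 0.081).

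The immediate-early list rose in the dark arm, with 0 of 19 called and 4 adjusted over the list alone (adjusted p = 3.6e-08, and adjusted p = 0.098 with an estimated correlation). Thalamus and choroid plexus lists fell there (medians -0.90 and -1.6, adjusted p = 0.00031 and 0.012), with adjusted p = 0.15 and 0.43 with an estimated correlation. The dark count of 1 stood beside 861 genes at an unadjusted p under 0.05. It was 11 without the filter on low values, 3 with only the groups compared, 7 with a term for Xist status, 3 with a Ttr term, 6 with terms for replicates 3 and 4 against 1 and 2 in each arm, where Fos and Egr1 were called, and 0 without the libraries under 2 M reads or without Dark ZT11.5 replicate 2, 3 or 4 or Dark ZT13 replicate 3. Flywch1 had adjusted p = 0.229 without Dark ZT13 replicate 3, and was not among the 3 genes called with only the groups compared. Without Dark ZT13 replicate 1 the count was 9, and without Dark ZT13 replicate 2 it was 3. The dusk change differed between the arms for 0 genes by limma, edgeR and DESeq2, with 548 at an unadjusted p under 0.05, 1 with a term for Xist status and 1 without Dark ZT13 replicate 2. Egr1 had the log2 difference of changes -1.15 (adjusted p = 0.091). The immediate-early list was lower in this difference (0 of 19 called, 2 adjusted over the list alone, adjusted p = 4.5e-08), with adjusted p = 0.1 with an estimated correlation.

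Over the 8 times of the day without light, 686 genes changed. In this arm the hours spent in darkness grew with the time of day, so their effects cannot be told apart. Cirbp, a cold-inducible RNA-binding protein gene, was highest at ZT13 (442 ± 91.9, n = 3) and lowest at ZT1 (176 ± 30, n = 3; adjusted p = 6e-08), and the related Rbm3 was 32.3 ± 8.24 at ZT13 and 12.8 ± 2.09 at ZT0 (adjusted p = 0.016). Pdia6, a protein folding enzyme of the ER, was highest at ZT18 (820 ± 21.8, n = 4) and lowest at ZT11.5 (528 ± 34.3, n = 4; adjusted p = 6e-08). Sgk1, a kinase gene induced by glucocorticoids, reached 498 ± 90 at ZT11.5 and 168 ± 13.9 at ZT18 (n = 4 each; adjusted p = 1.2e-05). Opalin, an oligodendrocyte membrane protein gene, was 221 ± 17.9 at ZT7.5 and 94.8 ± 17.4 at ZT3 (n = 4 each; adjusted p = 7.6e-07), and Plin4, a lipid droplet coat gene of the glucocorticoid list, was 27.8 ± 4.43 at ZT15 and 2.22 ± 2.44 at ZT1 (adjusted p = 2.1e-06). Cirbp lies on chromosome 10 (80165985 to 80172786, plus strand, GRCm38) and Opalin on 19 (41061710 to 41077113, minus strand).

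Glucocorticoid genes were enriched among genes changing over dark times, with 10 of 15 called and 13 adjusted over the list alone (Fisher's exact adjusted p = 6.4e-08), against 6.52% of all genes tested. Oligodendrocyte genes had 8 of 10 called and 9 adjusted over the list alone (1.4e-07), ER chaperones 9 of 14 and 10 (2.2e-07), heat shock genes 7 of 13 and 11 (3.2e-05), immediate-early genes 8 of 19 and 11 (5.5e-05), clock genes 7 of 16 and 9 (0.00012) and activity effectors 6 of 22 and 10 (0.0071). Microglia genes had 3 of 8 called and 4 adjusted over the list alone (0.033). These p-values take list members as independent and can be too small. The glucocorticoid list stood 0.57 ± 0.17 above ZT0 on the log2 scale at ZT11.5 and 0.23 ± 0.07 at ZT18, and the immediate-early list was at its lowest at ZT11.5, where Fos was 16.3 ± 3.65 and Egr1 369 ± 60.2. Cholesterol synthesis genes had 3 of 14 called and 11 adjusted over the list alone, and ribosomal protein genes 2 by either. The excitatory neuron list had 1 called and 3 adjusted over the list alone, the endothelial list 1 and 2, and the oxidative phosphorylation, interneuron, astrocyte, oligodendrocyte precursor and meningeal fibroblast lists 1 by either. Thalamus genes had 0 of 5 called and 3 adjusted over the list alone, the striatum list 0 and 1, and Alas2, the tested gene of the blood list, passed only by itself. No member of the choroid plexus, hippocampus or mural lists passed by either, nor did Xist, the tested gene of the sex list.

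Of the 686 genes, 170 were highest at ZT18 and 186 lowest at ZT11.5, and the median range over groups was 0.60 on the log2 scale, with 80 genes over 2-fold. There were 2573 at an unadjusted p under 0.05, and 1081 called by DESeq2. Without the 7 libraries under 2 M reads, 373 were called. Of these 7 libraries, the 5 dark ones were all from ZT13, ZT15 and ZT18. Mean depth was 3.4 M reads at Dark ZT0, 2.62 M at ZT11.5 and 2.19 M at ZT18. Dark ZT11.5 also had the highest thalamus list of the dark groups, 0.70 ± 0.54 above ZT0 on the log2 scale. The part of depth and thalamic tissue in these times of highest and lowest level was not tested.

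**Figure D3:**
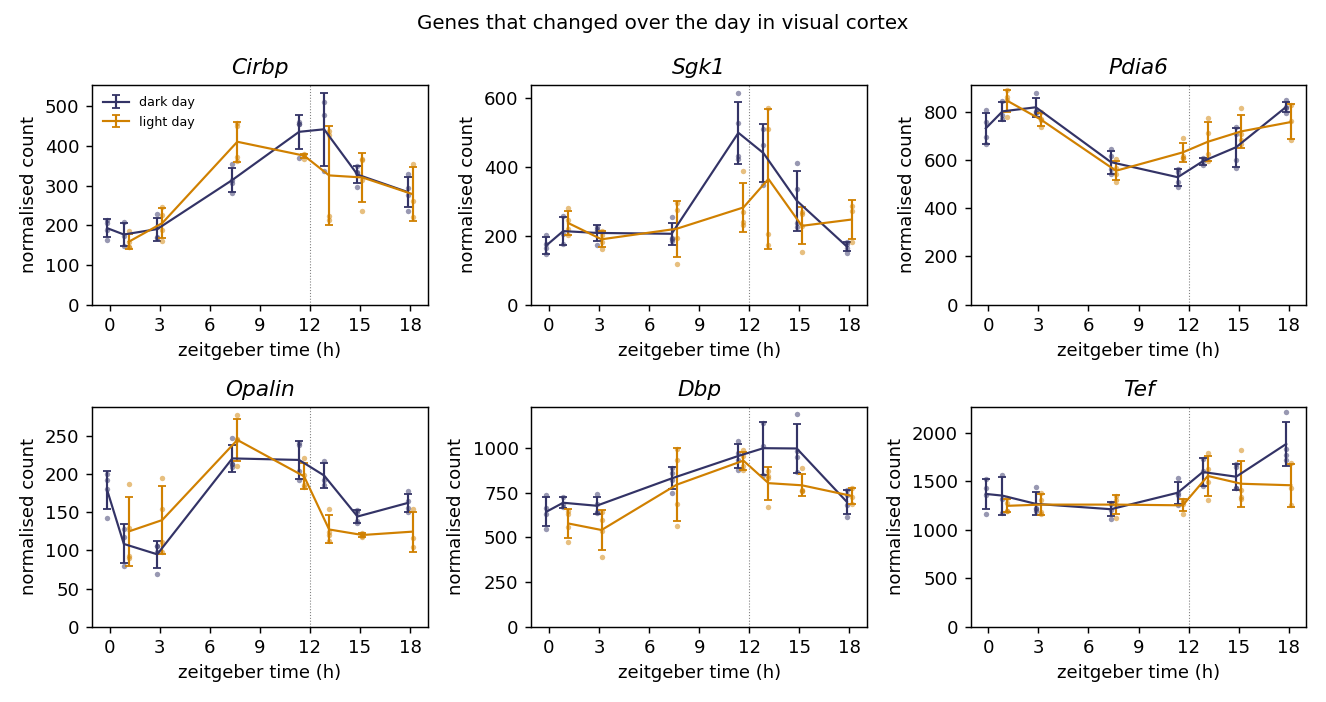
Normalised counts of Cirbp, Sgk1, Pdia6, Opalin, Dbp and Tef (vertical axes) against Zeitgeber time in hours (horizontal axes), with 1 point per library and group means ± SD, for the day with light and the day kept dark. On the dark day Cirbp runs from 176 at ZT1 to 442 at ZT13 and Sgk1 from 498 at ZT11.5 to 168 at ZT18.

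Over the 7 times of the light day, 401 genes changed, and 162 genes changed over time in both arms, against 26 for independent lists. Both tests used the same estimate of the spread per gene, so independent lists understate the overlap to be expected. Immediate-early genes led, with 15 of 19 called and 16 adjusted over the list alone (Fisher's exact adjusted p = 3e-17, against 3.81% of all genes), among them Egr4 (adjusted p = 2e-14) and Egr1 (5.2e-14). Activity effectors had 8 of 22 called and 14 adjusted over the list alone (9.1e-06), with Nptx2 at 169 ± 21.4 at ZT3 and 62.7 at ZT18. Glucocorticoid genes had 6 of 15 and 11 adjusted over the list alone (8.1e-05), heat shock genes 5 of 13 and 6 (0.00043), clock genes 5 of 16 and 11 (0.0011), oligodendrocyte genes 4 of 10 and 8 (0.0013), ER chaperones 4 of 14 and 5 (0.0048) and cholesterol synthesis genes 3 of 14 and 4 (0.04). Cirbp was 410 ± 50.7 at ZT7.5 and 158 ± 19.7 at ZT1 (n = 4 each; adjusted p = 8.4e-08), Opalin 245 at ZT7.5 and 120 at ZT15 (1.1e-05), and Hspa5, the main ER chaperone gene, 520 at ZT1 and 273 at ZT7.5 (1.9e-05). There were 1979 genes at an unadjusted p under 0.05, and 170 were called with only the groups compared.

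On the day without light several clock genes fitted a rhythm with the assumed period of 24 h. Sampling spanned 18 h of 1 day. Whether the change recurs, or is a drift with the hours in darkness, was not tested. In the dark arm 9 of the 16 clock genes fitted a 24 h rhythm, and 10 did so adjusted over the list alone. In the light arm 2 and 5 did. The dark arm had 30 libraries starting at ZT0 and the light arm 27 starting at ZT1. These counts therefore do not measure a difference between the arms. Dbp, a clock-controlled transcription factor gene on chromosome 7 (45705088 to 45710203, plus strand, GRCm38), peaked at ZT 11.7 in the dark arm and 12.1 in the light arm (adjusted p = 1.5e-05 and 1.6e-05), with peak over trough of 1.53 and 1.6. Per3, a period gene, peaked at ZT 14.6 and 15 (adjusted p = 0.00015 and 0.0022). Arntl, which encodes the clock activator BMAL1, peaked at ZT 1.1 in the dark arm (adjusted p = 0.001). Tef peaked at ZT 17.9 there (1.9e-05). The light rhythm of Tef did not pass (0.074), nor did its difference between the arms (0.78 over all genes). A rhythm differing between the arms was called for 1 clock gene adjusted over the list alone, Npas2 (adjusted p = 0.0069, peak at ZT 15.1 in dark and 6.9 in light), with adjusted p = 0.49 over all genes. Over all genes 0 differed by limma, with 681 at an unadjusted p under 0.05. The clock gene count was 2 by edgeR, 1 by DESeq2, 2 without Light ZT13 replicate 3 and 0 without the libraries under 2 M reads.

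Over the 22 lists and the light-dark, dawn and dusk contrasts, without the dusk difference between the arms, 59 of 242 pairs passed when adjusted over these pairs, and 13 with an estimated correlation. The astrocyte, endothelial and striatum lists passed in no light-dark contrast, with smallest adjusted p = 0.17, 0.19 and 0.1.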

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

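The splits that counted immediate-early members, the test with Prkcd and Tnnt1 as a term, and the alternative fits with that term, with Xist status and with terms for replicates 3 and 4 against 1 and 2 were chosen only after the results were seen.

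The light-dark difference varied with time of day for 19 genes (limma, adjusted p). These were Egr1 (4.1e-09), Egr4 (1.3e-08), Nr4a1 (3.6e-07), Fos (2e-06), Junb (0.00014), Egr2 (0.00055), Arc (0.00098), Midn (0.0022), Trib1 (0.0058), Gadd45b (0.0097), Sh2b3 (0.013), Egr3 (0.013), Bex1 (0.017), Ier2 (0.031), Dusp1 (0.031), Hsp90b1 (0.034), Slc30a9 (0.034), Klf4 (0.039) and Rpl37rt (0.039). Dusp1, Hsp90b1, Ier2 and Klf4 were among those lost without the filter on low values, and these and Egr3 among those lost without the libraries under 2 M reads. The rhythm of Npas2 differed between the arms with adjusted p = 0.0069 over the clock list alone.

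Immediate-early genes were higher in light at ZT11.5, with a median log2 difference of 0.73 over 19 genes. Depth as the cause was argued against, since with every library thinned to 1.64 M reads the median was 0.82 (SD 0.11 over 20 draws). Thalamic tissue in some dark libraries remains open as a partial cause, since with Prkcd and Tnnt1 as a term the median was 0.64, and from 0.52 to 0.93 when 1 library was left out. With that term Fos went from 2.66 to 2.5 and Egr1 from 1.70 to 1.64, while Arc went from 1.46 to 1.17 and no longer passed (adjusted p = 0.192). That light at the end of the day may hold these genes above their level on a dark day is a hypothesis, with the part owed to thalamic tissue open.

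The same libraries were also split in other ways to see how often chance gives as many genes. The real count and the highest of the other splits were 13 and 2 at ZT3, and 16 and 1 at ZT11.5. They were 32 and 2 for ZT1 against ZT0 in light, and 6 and 3 for the same hour in dark. In each of these 1 of 35 splits, the real one, gave as many, which argues against chance. It is the smallest share that 35 splits can give, so chance is not excluded. The dark count was also 0 without Dark ZT1 replicate 2, and its 3 named calls were lost with only the groups compared. For light against dark at ZT1 the real and highest other counts were 27 and 69. There 3 of 35 splits were as large, so chance cannot be excluded for the count of genes. The split with 69 set Dark ZT1 replicate 3 and Light ZT1 replicates 1, 2 and 4 against the rest, which points to a structure of the samples. For immediate-early genes called higher, the real and highest other counts were 13 and 0 at ZT1, and 6 and 0 at ZT3. At ZT11.5 they were 9 and 1. Each time 1 of 35 splits, the real one, was as large, which argues against chance without excluding it.

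At ZT13 the real count was 4 and the highest other 653, with 7 of 35 splits as large, so chance cannot be excluded. The split with 653 set Dark ZT13 replicates 1 and 3 and Light ZT13 replicates 1 and 2 against the rest, which points to a structure of the samples. At ZT7.5, ZT15 and ZT18 the real count was 0, which all 35 splits must reach, so that the splits say nothing on chance. The highest others were 2, 16 and 2. The split with 16 at ZT15 set replicates 1 and 2 against replicates 3 and 4, and the count at ZT15 was 0 with the replicate number as a block and 0 with terms for these pairs in each arm. For the dusk change in light the counts were 27 and 62, with 2 of 35 splits as large, so chance cannot be excluded. The split with 62 set replicates 1 and 2 against 3 and 4, and the count was 43 with the block and 47 with terms for these pairs in each arm. For the dusk change in dark they were 1 and 1, with 2 of 35 as large, so chance cannot be excluded.

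For the dusk difference between arms the real count was 0, which all 100 random splits must reach (value 100), so that the splits say nothing on chance, but the highest other count of 181 points to a structure of the samples. Of 100 random splits for each further result, 2 were as large for the light-dark difference varying with time (19 and 19). It was 1, the real one, for change over dark times (686 and 6) and over light times (401 and 136). For list and light-dark pairs (39 and 25) it was also 1. Chance was thus argued against for these totals, and not for each gene or list within them. The list pairs were at the preset correlation, where random arm labels alone gave up to 25. With an estimated correlation, the immediate-early, activity effector and excitatory neuron lists passed in 3, 6 and 1 light-dark contrasts. No other list tested did. For clock genes with a differing rhythm (1 and 4) 5 of 100 were as large, so chance cannot be excluded.

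Single libraries stood apart from the other 3 of their group in 10 of 156 pairs of group and measure, where chance gives about 1 in 20. Reads were 2.27 M in Dark ZT11.5 replicate 3 (others 2.7 to 2.78). The SD around the group mean was 0.273 in Dark ZT15 replicate 2 (others 0.259 to 0.261). The mean log2 level of activity effectors was 6.292 in Dark ZT7.5 replicate 1 (others 6.472 to 6.49) and 6.436 in Dark ZT15 replicate 3 (others 6.293 to 6.31). That of oligodendrocyte genes was 9.092 in Light ZT13 replicate 1 (others 9.152 to 9.159). That of thalamus genes was 6.635 in Dark ZT3 replicate 2 (others 4.971 to 5.242) and 5.399 in Light ZT1 replicate 4 (others 4.998 to 5.045). Egr1 was 701 in Dark ZT7.5 replicate 4 (others 559 to 575). Nptx2 was 68.5 in Light ZT1 replicate 3 (others 113 to 118) and 139 in Light ZT13 replicate 2 (others 67.4 to 77).

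Outside the genes tested, date-named entries of the table held at most 0.363% of a library's reads.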

How the results depend on the processing

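The fits with terms for Xist status, log2 Ttr, the first axis of variation within groups, Prkcd and Tnnt1, or replicates 3 and 4 against 1 and 2 within each arm, and the fit without 7 libraries under 2 M reads, were chosen only after seeing the data. Counts of genes within 1.5 times the reported count are not given, no result reversed, and TMM rescaling and a pseudocount of 5 moved no count beyond that. For the other values the cause was not tested, except where stated.

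Without the filter on low values the count was 4 at ZT3, 7 at ZT13, 7 at ZT18 and 11 for the dusk change in dark. With a minimum mean of 50 it was 12 for ZT1 against ZT0 in dark. With only the groups compared, which leaves fewer samples to estimate the spread, it was 2 at ZT13, 1 at ZT18, 0 for dawn in dark, 0 for dusk in light, 3 for dusk in dark and 170 for change over light times. By edgeR it was 2 for clock genes with a differing rhythm. By DESeq2 it was 23 at ZT3, 41 at ZT11.5, 1 at ZT18, 68 for dawn in dark, 99 for dusk in light, 1081 for change over dark times and 39 for a light-dark difference varying with time. With an estimated correlation 13 of 242 list pairs, the dusk difference left out, passed, against 59.

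With Xist status as a term the count was 7 for dusk in dark and 1 for the dusk difference. With a Ttr term it was 14 for dusk in light and 3 for dusk in dark. With the first axis as a term, which is orthogonal to the groups, it was 22 at ZT3, 32 at ZT11.5, 14 at ZT13, 10 at ZT18, 29 for dawn in dark, 75 for dusk in light, 10 for dusk in dark, 47 for a difference varying with time, 1678 over dark times and 838 over light times. The first axis was taken from what the groups left unexplained in these same libraries. It removes spread and leaves the fold changes alone, so higher counts are built in and are no sign of more changed genes. With terms for replicates 3 and 4 against 1 and 2 within each arm the count was 25 at ZT11.5 and 16 for dawn in dark. For dusk it was 47 in light and 6 in dark. With the term for Prkcd and Tnnt1 it was 8 at ZT3 and 14 for dusk in light. Without the libraries under 2 M reads, which leaves fewer samples, it was 1 at ZT13, 14 for dawn in dark, 0 for dusk in dark, 12 for a difference varying with time, 373 over dark times and 0 for the clock rhythm difference.

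With the replicate number as a block the dusk count in light was 43, and no other count moved beyond 1.5 times. The 6 calls it ended were Fosb at ZT3, Fosb, Npy and Rpl32 over dark times, and the oligodendrocyte and thalamus lists at ZT7.5. Between same-numbered libraries of both arms 5 of 25 correlations of deviations were over 0.1 (from -0.2 to 0.45). In all, 22 of 57 libraries were closest to their own number, a share that was not tested against chance. A pairing is thus not excluded, but single numbers were not taken to pair libraries across arms. Replicates 1 and 2 nonetheless stood apart from 3 and 4 within each arm, with Malat1 shifted in opposite directions in the arms, which 1 block for both arms cannot take up, and a batch of that kind is not ruled out.

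Leaving out 1 library at a time gave 17 to 28 genes at ZT1, 5 to 15 at ZT3, 0 to 0 at ZT7.5, 7 to 14 at ZT11.5, 1 to 5 at ZT13, 0 to 0 at ZT15 and 0 to 1 at ZT18. It gave 22 to 31 for dawn in light, 0 to 21 for dawn in dark, 3 to 70 for dusk in light, 0 to 9 for dusk in dark and 0 to 1 for the dusk difference. It gave 11 to 26 for a difference varying with time, 465 to 902 over dark times, 292 to 454 over light times and 1 to 2 for the clock rhythm difference. The libraries behind each change over 1.5 times are named with the results above.

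Among all values compared, each gene, list and count included, TMM rescaling left 2501 on the same side of the threshold and moved 0. DESeq2 left 2177, with 59 newly past it and 3 no longer past it, edgeR 2230, with 23 and 6, and the block 2478, with 17 and 6. Genes of small change were often missed at the depth and spread of these libraries, whose parts were not separated: in simulated data 35.8% of genes changed 1.5-fold were called for ZT1 and 53.7% for ZT7.5.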

Other observations

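All 3 tests of the pattern with Xist, and the gene comparison by Xist status, were chosen only after the result was seen. The tests of oligodendrocyte genes were not.

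Libraries with Xist above 20 and the others differed within groups at 64 genes besides Xist, which defines the split (limma with Xist status as a term), of which 32 were higher with Xist. Eif2s3x, an X-linked translation factor gene, was 0.56 higher on the log2 scale. The immediate-early list had Arc (0.51), Ier2 (0.40) and Npas4 (0.63) among the 64, all higher, and the activity effector list had Homer1, a synaptic scaffold gene, which was lower (-0.36). Cyr61 (0.69) and the metallothionein genes Mt1 (0.22) and Mt2 (0.24) were also higher. Camk2a, a kinase gene of excitatory neurons, had a difference of -0.17. The mean level of the glucocorticoid list was 0.13 higher (permutation p = 0.0019). The activity effector list differed by 0.01 (permutation p = 0.8) and the clock list by 0.02 (permutation p = 0.35).

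The immediate-early list was 0.20 higher on the log2 scale in libraries with Xist above 20, as a mean over the 14 groups that held both kinds, and higher in 11 of them (permutation p = 0.00043, 1e+05 resamples). Depth was argued against as the whole cause, since after log2 reads were taken out the difference was 0.16 (permutation p = 0.002). So was the Malat1 level of the libraries, with 0.18 after log2 Malat1 was taken out (permutation p = 0.00069), while RNA quality itself was not measured. A batch by replicate number stays open, since Xist followed replicates 3 and 4 in all but 2 libraries; in the Light ZT13 group, whose 4 libraries all had Xist, replicates 3 and 4 differed from 1 and 2 by -0.09, which with 4 libraries does not decide. The labels give no sex, but Xist and Y-linked reads split the libraries as female and male tissue would. This split nearly coincided with replicate number, so sex and such a batch cannot be told apart, and no biological explanation was tested.

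Oligodendrocyte genes changed over dark times, with 8 of 10 called and the list at -0.39 ± 0.18 relative to ZT0 (log2, mean ± SD) at ZT1 and at -0.35 ± 0.19 at ZT3. The test took a differing share of white matter to move the members alike. Of 10 members, 3 changed over time relative to the mean of the others: Opalin (adjusted p = 2.9e-06), Mal (5.5e-05) and Mobp (0.0022). Members that differ in how far they mark white matter could also move by unequal amounts, so this does not decide. A shift in all glia alike was not decided. Oligodendrocyte precursor means over the 8 dark groups had r = -0.2 and rho = -0.26 with the oligodendrocyte list (exact permutation p = 0.63 and 0.54, r = 0 without the 2 farthest groups). With 5 tested members, such a correlation over 8 groups cannot tell a differing course from noise. Astrocyte and microglia lists had r = 0.81 and 0.75. A daily change in some oligodendrocyte transcripts is a hypothesis that these values leave open. A share of white matter and a shift shared by glia stay open too, as a part or the whole of the change.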
